A study of Homo sapiens with 12 samples.

How the data were processed

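The samples were 12 cultures of C28/I2, an immortalised human chondrocyte line, in 4 groups of 3. The DMSO group received 0.5% DMSO. The SDF1 group received 50 nM SDF-1α, the chemokine also called CXCL12. The SDF1_AS4 group received 50 nM SDF-1α with 10 µM astragaloside IV, a saponin of Astragalus. The SDF1_SKHS group received 50 nM SDF-1α with 1% of SKHS, a traditional herbal formula. All were harvested after 48 h, and total RNA was sequenced. The labels name DMSO in the DMSO group alone, so whether the other 3 groups held the solvent is open, and the solvent cannot be told apart from SDF-1α in the comparison of SDF1 with DMSO. They name no vehicle for either product. A solvent added with a product therefore cannot be told apart from that product in its comparison with SDF1.

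The submitters' notes list Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 with the genome build GRCh38.p13, without giving the order of steps, and the headers of the authors' table name DESeq2 as the source of its tests. The deposited table holds 19215 gene symbols and, for each of 3 comparisons, a log2 fold change, a p-value and a q-value as the authors computed them. The log2 fold changes in the authors' table were taken as the second-named group over the first. This was checked on genes without a value in 1 comparison and with a value in another, taken as genes without reads in both groups of the first and so expressed in the group it leaves out, and all 1576 such values were on the side that this reading needs. The groups were matched to the table's headers through the sample titles. The q-value in the authors' table equals a Benjamini-Hochberg adjustment of its p-value over the genes with a value, with a largest difference of 1.29e-14, and is called adjusted p here. The table holds no value per sample, so the depth of each sample is unknown, no interval from counts was computed, and no sample could be checked against its group.

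From these values an implied standard error was computed for each gene as the size of the log2 fold change divided by the normal quantile of its p-value, which assumes the authors' p-values come from a Wald test. A value after ± is this implied standard error on the log2 scale, and 95% intervals were computed from it. Its median was 0.152 for SDF1 against DMSO, 0.155 for SDF1_AS4 against SDF1 and 0.144 for SDF1_SKHS against SDF1, and its highest value was 4.08 in each. The p-values measure only the spread between these samples of 1 cell line. A gene was called changed at an adjusted p under 0.05. The 3 comparisons that the table does not hold (SDF1_SKHS with SDF1_AS4, and each product group with DMSO) were computed from the difference or sum of the deposited log2 fold changes. Their standard error was set to the upper bound that adds both implied variances, since the spread of the shared SDF1 libraries cannot be taken out without values per sample, so their calls are conservative.

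Overlaps were counted over the 17821 genes with a value in all 3 deposited comparisons. Because every comparison used the same 3 SDF1 libraries, chance values of these libraries push SDF1 over DMSO and each product over SDF1 in opposite directions. They push both products over SDF1 in the same direction. Each overlap is therefore given beside 100 simulations in which the product changed no gene and the SDF1 libraries were shared, and beside the count that independence gives. The simulations gave the SDF1 group a fixed part, assumed and not estimated, of the smallest of the 3 squared standard errors. In the simulations of genes moved back or further a product had at most 3 changed genes, so their overlaps are near 0 by construction and do not show how the sharing tilts genes that a product changed. The way from p-value to call was tested on simulated data with 200 changed genes among 17436. At a 2-fold change 59.3% of the changed genes were recovered with the spread of SDF1 against DMSO, 69.9% with that of SDF1_AS4 against SDF1 and 68.1% with that of SDF1_SKHS against SDF1. At a 1.41-fold change the shares were 42.1%, 40.6% and 58.2%. Each share came from a single draw of 55 to 76 genes, so differences between the shares are not read as differences between the comparisons.

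Gene lists were tested with cameraPR in limma 3.58.1 (R 4.3.3) on the z statistics of all genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over lists within a comparison. Of 35 lists fixed in advance, 34 had at least 5 measured genes. The other, the protein-coding genes of the mitochondrial genome, had no measured member. Lists past the threshold were repeated at a preset correlation of 0.05, since a correlation estimated from the data needs values per sample. Transcript length, GC content, exon number, retained-intron transcripts and coordinates were taken from GENCODE 29 on GRCh38, in which 18730 symbols (97.5%) were found. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Trends with transcript length and GC content were removed with a lowess curve of span 0.3.

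Named genes were chosen by rule. For each deposited comparison these were the 6 largest rises and 6 largest falls among changed genes, the 4 smallest p-values in each direction, up to 3 changed members with the smallest p-values of each list past its threshold, and 12 genes fixed in advance (CXCL12, CXCR4, ACKR3, MMP1, MMP3, MMP13, ADAMTS5, COL2A1, ACAN, SOX9, IL6 and CXCL8). The rule for computed comparisons took 3 and 2 in place of 6 and 4. The planned minimum of log2 CPM of 2 and the planned separation of replicates could not be applied, and an implied standard error of at most 0.3 took their place for the largest rises and falls, set before the resulting genes were seen. Some genes that the rule names are not reported here. A gene named outside this rule is said to have been chosen after its values were seen.

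No edgeR fit of counts, which had been planned, could be run on a table without values per sample. For the same reason the changes of setting chosen in advance, with other normalizations, other tests, other count filters, a replicate block, each replicate left out in turn and other splits of the samples, could not be run. Alternatives that the table allows were run in their place: a minimum change of 2-fold, a stricter adjusted p of 0.01, only genes with a value in all comparisons, only genes with an implied standard error of at most 0.5, fold changes centred on the median of precise genes, a t distribution with 4 degrees of freedom, removal of the length and GC trends, equal group variances for the computed comparisons, and for the lists the correlation of 0.05 and a test on ranks.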

Results

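RNA was sequenced from 12 cultures of the human chondrocyte line C28/I2, with 3 cultures in each of 4 groups: DMSO, SDF1 (SDF-1α), SDF1_AS4 (SDF-1α with astragaloside IV) and SDF1_SKHS (SDF-1α with the herbal formula SKHS). The authors' deposited table gives 3 comparisons for 19215 genes, of which 17821 had a value in all 3, 788 in some and 606 in none. The depth of each sample is unknown, since the table holds comparisons and no counts. Values below are log2 fold changes from the authors' deposited table ± the implied standard error, and each rests on 3 cultures per group. The median log2 fold change of precisely measured genes, with an implied standard error of at most 0.3, was 0.04 for SDF1 over DMSO, -0.01 for SDF1_AS4 over SDF1 and 0.01 for SDF1_SKHS over SDF1.

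The comparison of SDF1 with DMSO asks what the chemokine did to these cells. Genes of sterol synthesis, cytosolic ribosomal proteins, glycolysis, the respiratory chain and p53 targets were higher with SDF-1α. Interferon-stimulated genes and DNA replication genes were lower. The list of the ATF4 pathway and the unfolded protein response was lower too, with a median of -0.14. That median was -0.03 once trends with transcript length and GC content were removed. DES, CNN1 and ACTG2, genes of muscle-type filaments, were among the largest rises, and MMP1, an interstitial collagenase, and ACAN, the core protein of aggrecan, fell. In all, 3122 of 18162 genes were higher and 3179 were lower, together 34.7%. Changes were mostly small, with a median size of 0.48 on the log2 scale among changed genes measured precisely. A change of at least 2-fold was reached by 123 higher and 870 lower genes, and among precisely measured genes by 61 and 536.

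The 6 largest rises with SDF-1α were those of KRT34, a hair keratin (1.85 ± 0.24, 3.61-fold), DES, the intermediate filament desmin (1.64 ± 0.22), KRTAP2-3, a keratin-associated protein (1.53 ± 0.15), CNN1, the actin-binding protein calponin 1 (1.50 ± 0.13), ACTG2, a smooth muscle actin (1.46 ± 0.13), and CGB5, a chorionic gonadotropin subunit (1.43 ± 0.12). The 6 largest falls were those of RAC3 (-2.55 ± 0.25, 5.88-fold lower), CELF6, an RNA-binding protein (-2.51 ± 0.13), XAF1, an interferon-inducible gene (-2.48 ± 0.28), SAPCD1 (-2.29 ± 0.20), AMH, anti-Müllerian hormone (-2.26 ± 0.16), and ZFP2, a zinc finger protein (-2.20 ± 0.24). The highest adjusted p among these 12 genes was 2.17e-12. KRTAP2-3 and CGB5 have near-identical neighbours in the genome, and how reads were shared between the copies is not known here. The smallest p-values in the upward direction belonged to NDRG1 (1.22 ± 0.08), FDFT1, which encodes squalene synthase (1.07 ± 0.07), INSIG1, a regulator of sterol synthesis (1.10 ± 0.08), and PDLIM1, a cytoskeletal LIM protein (1.13 ± 0.08). Downward they belonged to CCNL2, a cyclin of the splicing machinery (-1.59 ± 0.07, adjusted p = 7.6e-115), CELF6, COL7A1, the collagen of anchoring fibrils (-1.73 ± 0.09), and ANKRD10 (-1.41 ± 0.07). CCNL2 lies on chromosome 1 at 1385711 to 1399328, and KRT34 on chromosome 17 at 41377650 to 41382403 (GRCh38).

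Among genes of the chemokine's own axis, the receptor CXCR4 (chromosome 2, 136114349 to 136118165) had a log2 fold change of 0.00 ± 0.30, with a 95% interval from -0.59 to 0.59 and an adjusted p of 0.999. The scavenger receptor ACKR3 (chromosome 2, 236567787 to 236582358) rose by 0.43 ± 0.11. CXCL12 itself was measured imprecisely at -1.97 ± 1.05 and did not pass the threshold (adjusted p = 0.14). Of 24 measured genes of the axis, 11 rose and 2 fell, counts that were the same when adjusted over the list alone. The rises included the G protein subunits GNAI1 (0.74 ± 0.11) and GNAI3 (0.56 ± 0.10) and the chemokine-like cytokine MIF (0.46 ± 0.09). The list was higher than other genes with an adjusted p of 0.0215, and with adjusted p = 0.11 at a preset correlation of 0.05.

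Cartilage-degrading proteases and their inhibitors were lower on balance, with 13 of 29 genes falling and 2 rising, also when adjusted over the list alone (list adjusted p = 0.00816; adjusted p = 0.0745 at a correlation of 0.05). MMP1 was 2.29-fold lower (implied standard error 0.12 on the log2 scale, adjusted p = 1.02e-20). MMP3, the protease stromelysin 1, fell by 0.59 ± 0.07, the lysosomal protease CTSL by 0.61 ± 0.07 and MMP13, the main collagenase of cartilage, by 0.56 ± 0.18. Of 21 collagens and matrix genes of fibroblasts and dedifferentiated chondrocytes, 13 fell and 3 rose, with the same counts adjusted over the list alone and a median of -0.27 (adjusted p = 0.00816; adjusted p = 0.0604 at a correlation of 0.05 and 0.0563 with length and GC trends removed). COL6A1 (-1.26 ± 0.10), COL6A2 (-1.11 ± 0.11) and COL5A1 (-0.68 ± 0.09) led the falls. ACAN fell by 0.88 ± 0.15, while SOX9, the master transcription factor of chondrocytes, stood at -0.04 ± 0.10. COL2A1 (0.58 ± 2.68), ADAMTS5 (-1.27 ± 4.08) and IL6 (-0.10 ± 0.62) were too imprecise to show a change. The neutrophil chemokine CXCL8 rose by 0.63 ± 0.12.

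Metabolic groups rose with SDF-1α. Of 25 sterol synthesis genes, 20 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 0.60 and a list adjusted p of 4.65e-17. ACAT2, which makes acetoacetyl-CoA, was at 1.19 ± 0.09 in this list. Of 15 fatty acid synthesis genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00805, and 0.0516 at a correlation of 0.05), among them the desaturase SCD at 0.81 ± 0.07 and the malic enzyme ME1 at 0.57 ± 0.11, while SREBF1, the regulator of the pathway, fell by 0.45 ± 0.10. Of 33 hypoxia and glycolysis genes, 18 rose and 6 fell, the same adjusted over the list alone (adjusted p = 2.2e-05). NDRG1, the glycolytic kinase PGK1 (0.82 ± 0.07) and the mitophagy receptor BNIP3L (1.01 ± 0.09) rose. All 56 measured ribosomal protein genes rose, also adjusted over the list alone, with a median of 0.48 (adjusted p = 2.72e-24), led by RPL30 (0.67 ± 0.07), RPLP0 (0.66 ± 0.08) and RPS27 (0.73 ± 0.10). Of 40 nuclear-encoded subunits of the respiratory chain, 28 rose and 1 fell (29 and 1 adjusted over the list alone), with a median of 0.31 (adjusted p = 4.44e-07), among them COX6C (0.74 ± 0.11), COX7A2 (0.55 ± 0.09) and SDHC (0.54 ± 0.09). With the trends in transcript length and GC content removed, these medians were 0.33 for the ribosomal proteins and 0.21 for the respiratory chain.

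The cell cycle genes moved in both directions. Of 36 replication and G1/S genes, 20 fell and 2 rose (20 and 3 adjusted over the list alone; adjusted p = 0.000638), including the licensing factor CDT1 (-0.71 ± 0.10), the chromatin assembly subunit CHAF1A (-0.68 ± 0.10) and the repressor E2F8 (-0.83 ± 0.13). Of 35 G2/M and mitosis genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone; adjusted p = 0.00478, and 0.0604 at a correlation of 0.05), including DLGAP5 (0.74 ± 0.10), cyclin B2 gene CCNB2 (0.61 ± 0.09) and the kinesin KIF20A (0.53 ± 0.08). Of 26 p53 targets, 17 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.000254), with the cell cycle inhibitor CDKN1A at 0.82 ± 0.08, CCNG1 at 0.73 ± 0.10 and BTG2 at 1.22 ± 0.18.

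Of 36 interferon-stimulated genes, 24 fell and none rose (24 and 1 adjusted over the list alone), with a median of -0.61 (adjusted p = 1.62e-10). BST2, the restriction factor tetherin, was at -1.60 ± 0.13, the transcription factor STAT2 at -1.11 ± 0.10 and the RNA sensor OAS1 at -1.37 ± 0.12. Of 32 genes of the ATF4 pathway and the unfolded protein response, 15 fell and 3 rose (15 and 4 adjusted over the list alone). The list adjusted p was 0.000234, and 0.0440 on ranks. The median of this list was -0.14, and -0.03 with length and GC trends removed (adjusted p = 0.000379). The falls were led by HSPA5, the chaperone BiP (-1.13 ± 0.07), SLC3A2, a subunit of amino acid transporters (-1.06 ± 0.09), and HSP90B1, the chaperone GRP94 (-0.74 ± 0.07). Of 28 NRF2 targets, 12 rose and 6 fell (14 and 6 adjusted over the list alone; adjusted p = 0.0159, 0.108 at a correlation of 0.05 and 0.0545 with length and GC trends removed), led by the ferritin chains FTL (0.81 ± 0.10) and FTH1 (0.62 ± 0.08) and the peroxiredoxin PRDX1 (0.54 ± 0.08). Of 24 TGF-beta and BMP targets, 8 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0075, and 0.0604 at a correlation of 0.05), and the rises were led by the contractile genes ACTA2 (1.29 ± 0.10), TAGLN (1.18 ± 0.09) and CNN1. Of 14 glucocorticoid targets, 7 rose, also adjusted over the list alone (adjusted p = 0.00969, and 0.0584 at a correlation of 0.05), including MT1X (0.64 ± 0.09), GLUL (0.48 ± 0.08) and ERRFI1 (0.55 ± 0.10). The median of this list was 0.26 and its mean -0.03, since imprecise members such as ANGPTL4 (-2.78 ± 2.61) weigh on the mean.

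In all, 16 of 34 lists passed for SDF1 over DMSO, 11 higher and 5 lower, and 8 of the 16 passed at a correlation of 0.05. Genes lower with SDF-1α had a median GC content of 54.5% in their transcripts against 46.9% for genes that were higher, and 65.0% of them had an annotated retained-intron transcript against 53.7%. With a t distribution of 4 degrees of freedom in place of the normal one, 1092 genes passed. The labels name the solvent DMSO in the DMSO group alone, so this comparison cannot separate SDF-1α from a difference in solvent.

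The comparison of SDF1_AS4 with SDF1 asks what astragaloside IV changed in cells that also received the chemokine. EGR1, an immediate early transcription factor, fell by 0.92 on the log2 scale ± 0.13 (1.89-fold lower, adjusted p = 4.73e-08). It had risen by 1.17 ± 0.14 in SDF1 over DMSO. The same SDF1 libraries stand in both values, so a high level of EGR1 in those libraries alone would give both. Collagens and matrix genes of fibroblasts, YAP targets, replication genes and, at a correlation of 0.01 but not 0.05, mitosis genes were lower as groups, and ribosomal proteins and respiratory chain subunits were higher as groups, by small amounts that were near 0 in the median once trends with transcript length and GC content were removed (from 0.21 to -0.00 and from 0.24 to 0.02). At the level of single genes, 36 of 18133 were higher and 29 lower, 0.358% in all, with a median size of 0.44. The count was 190 when only genes with an implied standard error of at most 0.5 were tested, and 7 at an adjusted p of 0.01. An unadjusted p under 0.05 was reached by 2970 genes. A change of at least 2-fold was reached by 4 genes, all higher and all with an implied standard error above 0.3. Chosen after their values were seen, these were LDLRAD2 (3.26), MEF2B (1.33), VIL1 (2.83) and ZASP (9.33).

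The largest rises with astragaloside IV among precisely measured genes were those of UPK3BL2 (0.74 ± 0.16), UPK3BL1 (0.62 ± 0.13), CASTOR2 (0.59 ± 0.12), C4orf48 (0.57 ± 0.14), SYN3, a synapsin (0.55 ± 0.11), and C9orf16 (0.54 ± 0.11). UPK3BL1 and UPK3BL2 are near-identical copies, so their rises cannot be counted as separate. The largest falls after EGR1 (chromosome 5, 138465490 to 138469315) were those of TVP23C-CDRT4, a read-through transcript (-0.88 ± 0.23), CCNE2, which encodes cyclin E2 (-0.86 ± 0.22), APC, a Wnt pathway inhibitor (-0.57 ± 0.15), LGR4, an R-spondin receptor (-0.57 ± 0.14), and ZBTB38 (-0.54 ± 0.14). The highest adjusted p among these 12 genes was 0.0476. ZASP had the smallest p-value upward at 9.33 ± 1.49, an imprecise value whose 95% interval runs from 6.41 to 12.25. The matricellular gene THBS1 (-0.49 ± 0.11), AHNAK (-0.47 ± 0.11) and TNC, which encodes tenascin C (-0.45 ± 0.11), followed EGR1 among the smallest p-values downward. None of the 12 genes fixed in advance passed the threshold. CXCR4 stood at -0.21 ± 0.30 with a 95% interval from -0.79 to 0.38, ACKR3 at 0.05 ± 0.11, MMP1 at 0.06 ± 0.13, MMP3 at 0.14 ± 0.08, MMP13 at 0.12 ± 0.17, ACAN at -0.30 ± 0.15, SOX9 at -0.00 ± 0.10 and CXCL8 at -0.14 ± 0.13. CXCL12, ADAMTS5, COL2A1 and IL6 had standard errors between 0.65 and 3.18.

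For SDF1_AS4 over SDF1, 7 of 34 lists passed, 4 lower and 3 higher, and 6 of the 7 passed at a correlation of 0.05. The collagens and matrix genes had a median of -0.26, with 2 of 21 falling (THBS1 and TNC) and 8 adjusted over the list alone (adjusted p = 1.45e-05). The YAP targets had a median of -0.20, with 0 of 20 past the threshold and 9 lower adjusted over the list alone (adjusted p = 1.59e-05). Of 36 replication genes, 1 fell (CCNE2) and 4 were lower adjusted over the list alone (adjusted p = 6.94e-05). Of 35 mitosis genes, 1 fell, the cytokinesis gene ANLN (-0.40 ± 0.11), and 6 were lower and 1 higher adjusted over the list alone (adjusted p = 0.00144, and 0.0523 at a correlation of 0.05). Of 56 ribosomal protein genes, 0 passed over all genes and 26 were higher adjusted over the list alone, with a median of 0.21 (adjusted p = 2.34e-21). Of 40 respiratory chain subunits, 0 passed and 20 were higher adjusted over the list alone, with a median of 0.24 (adjusted p = 2.32e-13). Of 28 NRF2 targets, 0 passed and 8 were higher and 1 lower adjusted over the list alone, with a median of 0.17 (adjusted p = 0.00105).

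The fold change with astragaloside IV followed transcript length and GC content across genes. Spearman's rho across 11892 precisely measured genes, which are not independent replicates, was -0.535 with length and 0.589 with GC content, against -0.137 and -0.206 for SDF1 over DMSO and -0.106 and 0.0409 for SDF1_SKHS over SDF1. In 10 equal bins of GC content, the lowest bin (median 37.2%) had a median log2 fold change of -0.17 and the highest (64.2%) of 0.21. The 34 annotated genes that were higher had a median length of 1720 nucleotides and a GC content of 60.8%, and the 29 that were lower 5931 nucleotides and 44.1%. With both trends removed, 8 of the 63 annotated changed genes were still past the threshold, and the medians moved from 0.21 to -0.00 for ribosomal proteins, from 0.24 to 0.02 for the respiratory chain, from 0.17 to 0.03 for NRF2 targets, from -0.26 to -0.12 for the collagens, from -0.20 to -0.13 for YAP targets and from -0.14 to -0.08 for mitosis genes, and that of replication genes stayed at -0.12. The ribosomal proteins then had a list adjusted p of 0.0417 in the upward direction, although their median was not above 0, the respiratory chain 0.0134 and the NRF2 targets 0.0542. The share of changed genes that were higher was 55.4% as deposited, 66.7% after centring on the median of precise genes and 78.1% with the trends removed. With a t distribution of 4 degrees of freedom 0 genes passed. Its heavier tails raise every p-value, so the count can only fall by construction. This 0 does not show that no gene changed.

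**Figure D1:**
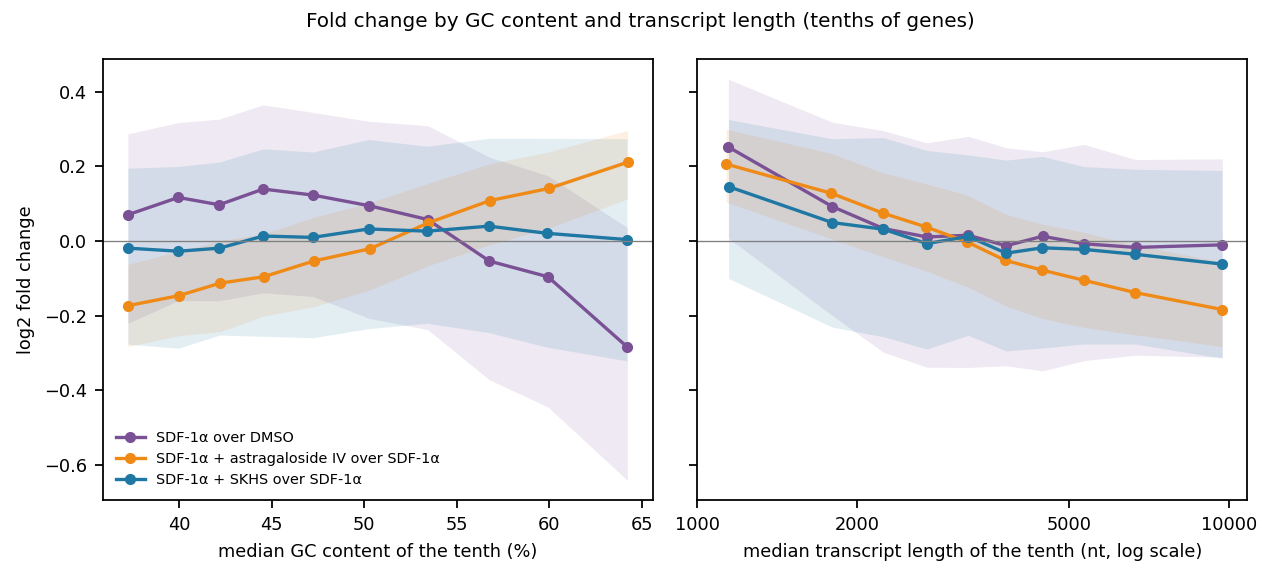
Median log2 fold change (lines) and quartiles (shading) of precisely measured genes, in 10 equal bins of GC content (percent) and of transcript length (nucleotides, log axis), for the 3 deposited comparisons. For SDF1_AS4 over SDF1 the medians run from -0.17 in the lowest to 0.21 in the highest bin of GC content.

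The comparison of SDF1_SKHS with SDF1 asks what the herbal formula changed in cells that also received the chemokine. The list of the ATF4 pathway and the unfolded protein response, p53 targets and NRF2 antioxidant genes were higher as groups, with several genes more than 4-fold higher, although 7 of the 32 genes of the first list fell. Mitosis and replication genes fell almost without exception, and sterol synthesis genes, collagens and matrix genes of fibroblasts and hypoxia and glycolysis genes fell as groups. CXCR4 fell by 1.64 on the log2 scale ± 0.36 (3.11-fold lower, adjusted p = 3.63e-05), and ACKR3 rose by 0.82 ± 0.08. In all, 2877 of 18251 genes were higher and 3041 lower, together 32.4%, with a median size of 0.46 (1.38-fold). A change of at least 2-fold was reached by 310 higher and 515 lower genes, and among precisely measured genes by 183 and 392.

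The largest rises with SKHS were those of ADM2, an adrenomedullin-family peptide (4.07 ± 0.19, 16.8-fold), GDF15, a stress-induced cytokine (3.97 ± 0.15, 15.7-fold), SPX, the peptide spexin (3.20 ± 0.27), TRIB3, a pseudokinase (2.99 ± 0.10), CHAC1, a glutathione-degrading enzyme (2.98 ± 0.10), and SLC7A5, a transporter of large neutral amino acids (2.97 ± 0.09, adjusted p = 4.73e-251). ASNS, asparagine synthetase, was at 2.49 ± 0.08. The largest falls were those of PIF1, a DNA helicase (-2.64 ± 0.20, 6.23-fold lower), PCYOX1L (-2.43 ± 0.16), FAM83D, a spindle protein (-2.16 ± 0.09), RBFOX3, a splicing factor (-2.15 ± 0.28), MXD3, a MAX dimerization protein (-2.14 ± 0.13), and CENPE, a kinetochore motor (-2.12 ± 0.13). The smallest p-values downward belonged to KIF20A (-1.91 ± 0.08), the mitotic kinase PLK1 (-1.75 ± 0.07), FAM83D and MEGF6 (-1.84 ± 0.08). The highest adjusted p among the genes of these sentences was 1.4e-13. GDF15 lies on chromosome 19 at 18374731 to 18389176, SLC7A5 on chromosome 16 at 87830023 to 87869488 and CDKN1A on chromosome 6 at 36676460 to 36687339 (GRCh38).

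Among the genes fixed in advance, MMP13 (chromosome 11, 102942995 to 102955734) fell by 1.07 on the log2 scale ± 0.19 with SKHS, MMP3 (chromosome 11, 102835801 to 102843803) by 0.75 ± 0.07, MMP1 (chromosome 11, 102789920 to 102798160) by 0.42 ± 0.13, CXCL8 by 1.46 ± 0.13, ACAN by 0.41 ± 0.15 and SOX9 by 0.40 ± 0.10. CXCL12 (-0.64 ± 1.53), ADAMTS5 (2.36 ± 2.78), COL2A1 (-0.08 ± 2.30) and IL6 (-0.21 ± 0.58) were too imprecise to show a change. As groups, the genes of the chemokine axis (adjusted p = 0.187) and the matrix proteases (adjusted p = 0.105) did not pass the list test.

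The cell cycle lists showed the broadest falls with SKHS. All 35 measured mitosis genes fell, also adjusted over the list alone, with a median of -1.56 (adjusted p = 5.05e-138), among them the proliferation marker MKI67 at -1.97 ± 0.09. Of 36 replication genes, 35 fell and 1 rose, the same adjusted over the list alone, with a median of -0.73 (adjusted p = 3.07e-29), including the ribonucleotide reductase subunit RRM2 (-1.51 ± 0.08), the flap endonuclease FEN1 (-1.38 ± 0.09) and the polymerase subunit POLA1 (-1.38 ± 0.09). Of 26 p53 targets, 24 rose and 1 fell, the same adjusted over the list alone, with a median of 0.96 (adjusted p = 2.4e-37), led by GDF15, CDKN1A (1.69 ± 0.07) and SESN2, a stress-induced inhibitor of mTORC1 signalling (2.04 ± 0.09). Histone genes were higher as a list (adjusted p = 0.000126), with 6 of 20 rising, also adjusted over the list alone. Their median was 0.84, and 0.64 with length and GC trends removed, and most members did not pass. H1-2 (2.29-fold) and H2AC6 (1.66 ± 0.13) were among the rises, and how reads were shared between near-identical histone genes is not known here.

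Of 32 genes of the ATF4 pathway and the unfolded protein response, 20 rose and 7 fell (20 and 8 adjusted over the list alone), with a median of 0.93 (adjusted p = 3.86e-47). The rises were led by SLC7A5, ASNS and TRIB3, which belong to the amino acid response. The 7 falls, named after their values were seen, were those of MANF (-0.97), EDEM1 (-0.65), HSP90B1 (-0.44), CALR (-0.44), DNAJB9 (-0.44), PDIA4 (-0.39) and CRELD2 (-0.27), which act in protein folding or degradation in the endoplasmic reticulum. Of 28 NRF2 targets, 23 rose and none fell, also adjusted over the list alone, with a median of 0.58 (adjusted p = 2.01e-23), led by the cystine transporter SLC7A11 (2.37 ± 0.10), which is also in the ATF4 list, SRXN1, which encodes sulfiredoxin (1.38 ± 0.07), and the quinone reductase NQO1 (1.18 ± 0.07). Of 13 aryl hydrocarbon receptor targets, 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.000467). SLC7A5 and STC2 (0.69 ± 0.06), which led this list with NFE2L2, the gene of NRF2 itself (0.68 ± 0.07), are also in the ATF4 list, and the list did not pass on ranks (adjusted p = 0.529). Of 18 heat shock genes, 11 fell and 1 rose (11 and 2 adjusted over the list alone; adjusted p = 9.2e-06), including HSPA1A (-1.17 ± 0.08) and HSPA1B (-1.19 ± 0.09), near-identical copies, and CHORDC1 (-1.39 ± 0.11).

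Of 25 sterol synthesis genes, 23 fell with SKHS and none rose (24 and 0 adjusted over the list alone), with a median of -0.83 (adjusted p = 1.53e-36). INSIG1 was at -1.30 ± 0.07 and HMGCS1, an enzyme of the mevalonate pathway, at -1.53 ± 0.09. Of 15 fatty acid synthesis genes, 8 fell and 2 rose, also adjusted over the list alone (adjusted p = 8.2e-05), among them SCD (-0.83 ± 0.06), FASN, fatty acid synthase (-0.95 ± 0.08), and ELOVL5 (-1.15 ± 0.10). Of 33 hypoxia and glycolysis genes, 20 fell and 1 rose, also adjusted over the list alone (adjusted p = 1.49e-08). PGK1 (-0.82 ± 0.06) and ALDOC (-1.33 ± 0.10) fell, and the gene that rose was VEGFA, an angiogenic growth factor (2.63-fold). Of 21 collagens and matrix genes, 15 fell and none rose, also adjusted over the list alone, with a median of -0.33 (adjusted p = 7.92e-11), led by the collagen-modifying enzymes PLOD2 (-1.47 ± 0.10) and LOX (-1.16 ± 0.08) and by COL1A2 (-0.97 ± 0.07). Of 56 ribosomal protein genes, 46 rose and none fell (47 and 0 adjusted over the list alone), with a median of 0.28 (0.17 with length and GC trends removed; adjusted p = 7.92e-11), among them RPL4 (0.48 ± 0.06) and RPS19 (0.56 ± 0.08).

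Of 36 interferon-stimulated genes, 14 rose with SKHS and 2 fell, also adjusted over the list alone (adjusted p = 0.00841, and 0.0982 at a correlation of 0.05), including ISG15 (0.73 ± 0.09), IFI27 (1.06 ± 0.13) and the peptide transporter TAP1 (0.72 ± 0.09). Of 24 TGF-beta and BMP targets, 10 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.0297, 0.121 at a correlation of 0.05 and 0.379 on ranks), with SMAD6 2.64-fold higher, PMEPA1 at 1.04 ± 0.08 and TGFBI among the falls (adjusted p = 3.99e-24). Of 20 YAP targets, 7 rose and 5 fell (7 and 6 adjusted over the list alone; adjusted p = 0.0301, 0.117 at a correlation of 0.05, 0.379 on ranks and 0.0608 among genes with a standard error of at most 0.5), with DLC1 at 1.19 ± 0.08, AJUBA at 0.80 ± 0.06 and ANKRD1 at 0.68 ± 0.06. In all, 16 of 34 lists passed for SDF1_SKHS over SDF1, 9 higher and 7 lower, and 13 of the 16 passed at a correlation of 0.05. With a t distribution of 4 degrees of freedom, 1350 genes passed.

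**Figure D2:**
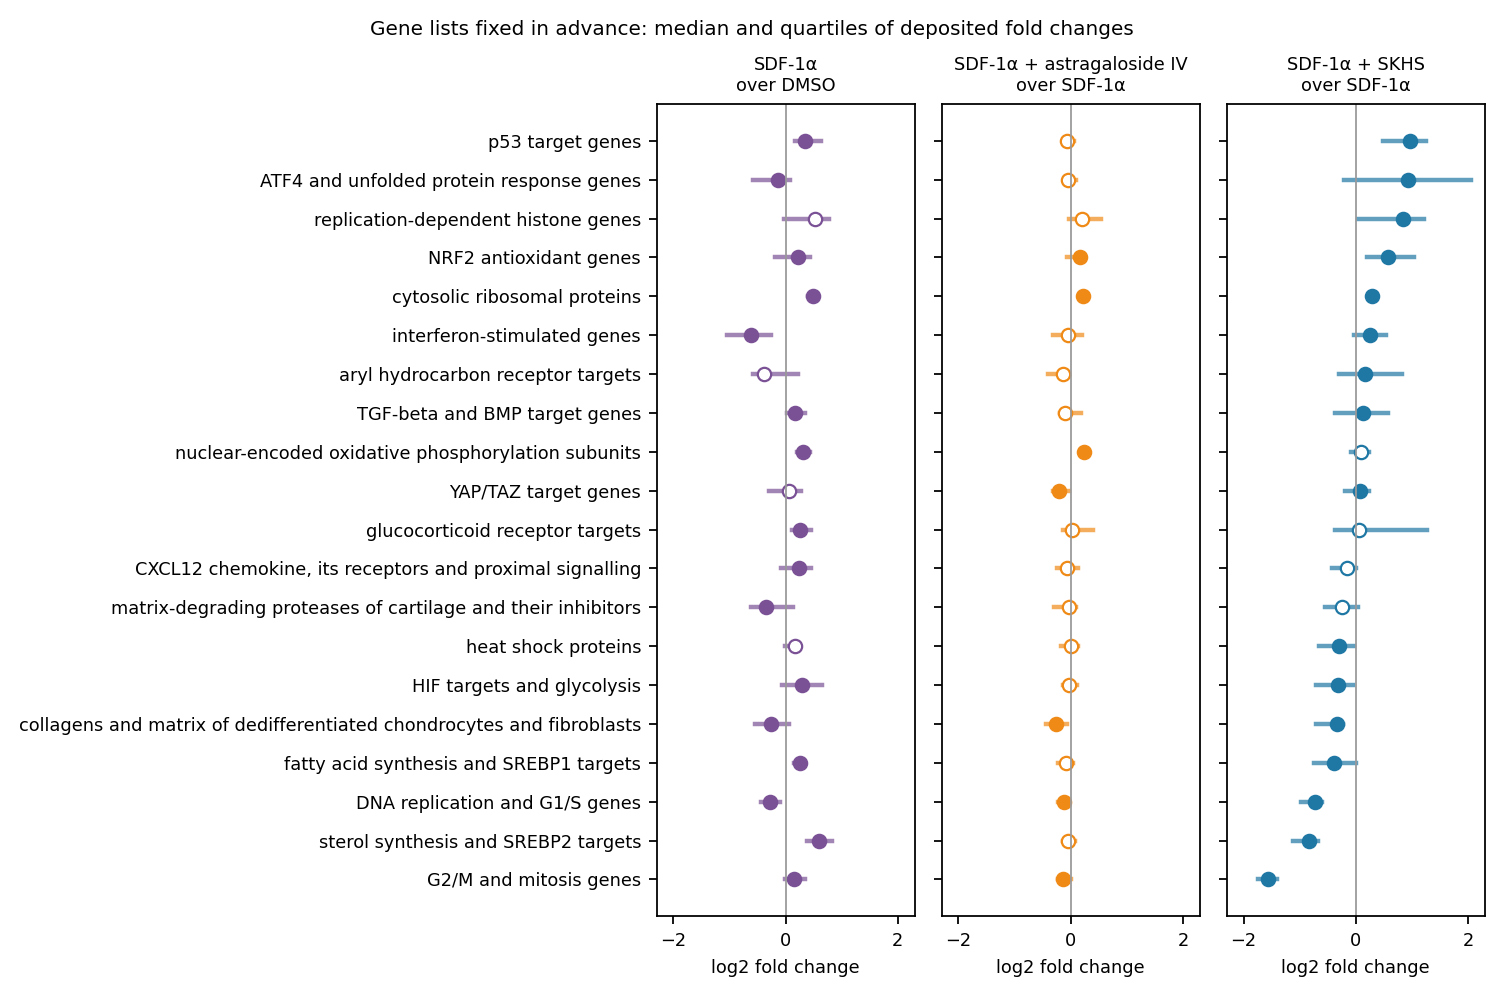
Median log2 fold change of each gene list (points), with the quartiles of its members (bars), for the 20 lists past the threshold in at least 1 of the 3 deposited comparisons, filled where the list passed and open where it did not. The mitosis genes with SKHS lie at a median of -1.56, and the ATF4 and p53 lists with SKHS at 0.93 and 0.96.

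Across the 3 deposited comparisons, 20 of the 34 tested lists passed at least once. The 14 that passed in none were those of cartilage matrix, chondrocyte hypertrophy, NF-kB and inflammation, early response to MAP kinases, apoptosis, Wnt targets, metallothioneins, lysosome and autophagy, and the 6 lists of other cell types or lines (leukocyte, endothelial, epithelial, osteoblast and adipocyte markers and genes of other human lines). The adjusted p of these 6 lists ranged from 0.313 to 0.925 for SDF1 over DMSO, from 0.863 to 0.895 for SDF1_AS4 over SDF1 and from 0.428 to 0.973 for SDF1_SKHS over SDF1.

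The series asks whether the products act against the response to SDF-1α, and the direct count is of genes that changed with SDF-1α and then moved back with a product. A solvent held by the DMSO group and a product group but not by the SDF1 group would also move genes back. The labels leave this open. Of 6300 genes changed with SDF-1α, 25 (0.397%) moved back with astragaloside IV and 12 moved further in the same direction. These counts were 73 and 41 with only genes of an implied standard error of at most 0.5, 19 and 16 with length and GC trends removed, 3 and 1 at an adjusted p of 0.01, and 0 and 0 with a t distribution of 4 degrees of freedom. The last pair was bound to be 0, since no gene passed for SDF1_AS4 over SDF1 in that setting. EGR1 was among the 25. Of the 25 genes, 13 were higher with SDF-1α and then lower, against 5.08 at independence, and 12 were lower and then higher, against 6.42. Of the 12 moved further, 10 were higher again, against 6.31 at independence, and 2 were lower again, against 5.17. Among precisely measured genes, 23 moved back against 14.5 at independence and 12 moved further against 14.6. In 100 simulations of an unchanged product that shared the SDF1 libraries, the highest count was 1 moved back and 0 moved further, and a simulation had at most 1 changed gene against 65, so these counts were bound to be near 0. In SDF1_AS4 over DMSO, 20 of the 25 were not past the threshold and 5 were still changed on the side of SDF-1α. Calls over DMSO are conservative, so the 20 are not shown to be back at the DMSO level. Across 11768 genes the covariance of the fold changes was -0.0134 against -0.0078 in the simulations, and Pearson's r was -0.142 against -0.121. The simulated values rest on a spread assumed for the SDF1 libraries, and a larger one would make them more negative. They do not show whether astragaloside IV opposed SDF-1α.

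With SKHS, 1101 of the 6300 genes (17.5%) moved back and 1886 (29.9%) moved further, against a simulated highest of 2 moved back and 0 moved further, where a simulation had at most 3 changed genes against 5915. Of those moved back, 645 were higher and then lower, against 533 at independence, and 456 were lower and then higher, against 513. Of those moved further, 946 were higher again, against 503 at independence, and 940 were lower again, against 542. Among precisely measured genes, 1064 moved back against 1345 at independence and 1824 moved further against 1337. The covariance across genes was 0.0299 against a simulated -0.0078, and Pearson's r was 0.14 against a simulated -0.131, across genes that are not independent replicates. Of the 1101 genes moved back, 830 were not past the threshold in SDF1_SKHS over DMSO, 130 were still changed on the side of SDF-1α and 141 were changed on the other side. Calls over DMSO are conservative, since their standard error is an upper bound. Picking genes for opposite signs over shared libraries also favours a small sum. The 830 are therefore not shown to be back at the DMSO level. INSIG1, SCD and PGK1 rose with SDF-1α and fell with SKHS, CDKN1A and BTG2 rose with both, and MMP1, MMP3 and MMP13 fell with both. The call of moved back or further counts genes of any size, and with at least a 2-fold change in each step 37 genes moved back and 82 moved further.

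**Figure D3:**
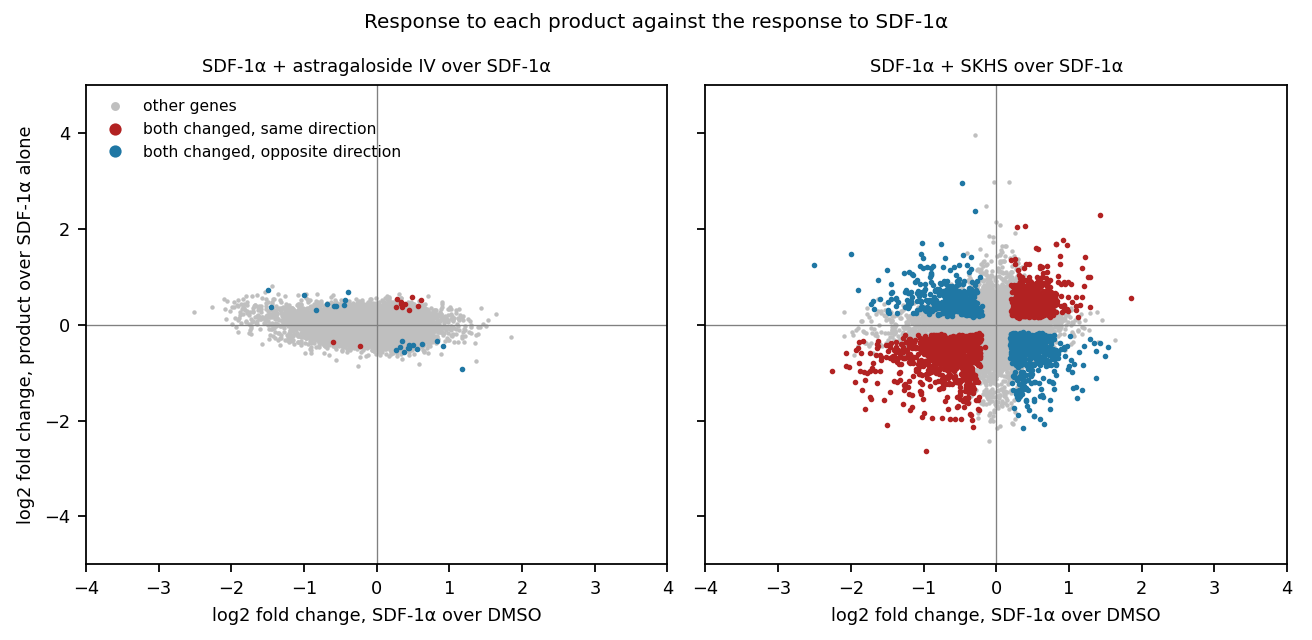
Log2 fold change of SDF1 over DMSO (horizontal axis) against that of each product group over SDF1 (vertical axis) for precisely measured genes, with genes that moved back in blue, genes that moved further in red and other genes in grey. Over all genes, 1101 of 6300 SDF-1α-changed genes moved back and 1886 further with SKHS, and 25 and 12 with astragaloside IV.

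Both products changed 35 genes in the same direction, 16 higher against 5.81 at independence and 19 lower against 4.95, and 10 in opposite directions. Both comparisons use the same SDF1 libraries. Chance values of these libraries push both fold changes the same way, so independence is too low a baseline for the 35. Simulations in which neither product changed a gene gave a highest count of 0 such genes, which that setting leaves near 0 by construction. The covariance was 0.0154 against a simulated 0.0078, while Pearson's r was 0.161 against a simulated 0.433. The simulated values rest on a spread assumed for the SDF1 libraries and on products without effects. They do not decide whether the products share a response. EGR1 was lower with both, at -0.92 ± 0.13 with astragaloside IV and -1.36 ± 0.12 with SKHS. It was higher in SDF1 over DMSO, and a high level in the shared SDF1 libraries alone would give this pattern.

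In SDF1_SKHS over SDF1_AS4, computed from the deposited comparisons, 1524 of 17927 genes were higher and 1865 lower. GDF15 (4.19 ± 0.29), SLC7A5 (3.12 ± 0.16), CHAC1 (3.06 ± 0.18) and ASNS (2.59 ± 0.13) were higher with SKHS than with astragaloside IV, and PIF1 (-2.94 ± 0.25), MXD3 (-2.44 ± 0.17), PCYOX1L (-2.40 ± 0.20), PLK1 (-1.87 ± 0.10) and KIF20A (-1.89 ± 0.11) were lower. The products differed for CXCR4 (-1.43 ± 0.47, adjusted p = 0.0154), MMP13 (-1.19 ± 0.25), MMP3 (-0.89 ± 0.11) and CXCL8 (-1.32 ± 0.18), each lower with SKHS. The difference was -0.11 ± 0.22 for ACAN, which did not pass. Of 34 lists, 16 passed, 8 higher and 8 lower, and 12 of the 16 passed at a correlation of 0.05. Metallothioneins were among the lower lists (adjusted p = 0.0268), with MT1X at -1.91 ± 0.14 and MT2A at -1.46 ± 0.21. With equal variances in the groups 5708 genes passed, and with a t distribution of 4 degrees of freedom 0 passed, where an unadjusted normal p under 0.05 was reached by 4890.

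In SDF1_AS4 over DMSO, 1935 of 17895 genes were higher and 2079 lower. DES (1.85 ± 0.27), CGB5 (1.78 ± 0.15), KRTAP2-3 (1.62 ± 0.20) and TAGLN (1.37 ± 0.13) were higher, and CELF6 (-2.25 ± 0.21), ZMAT1 (-1.98 ± 0.27), FAM153A (-1.98 ± 0.16), COL7A1 (-1.76 ± 0.13) and CCNL2 (-1.47 ± 0.11) were lower. MMP1 was at -1.14 ± 0.18, ACAN at -1.18 ± 0.22 and ACKR3 at 0.48 ± 0.15, each past the threshold, and CXCR4 was at -0.21 ± 0.42, which did not pass. Of 34 lists, 15 passed, 10 higher and 5 lower, and 12 of the 15 passed at a correlation of 0.05. Ribosomal proteins (adjusted p = 2.62e-44), respiratory chain (3.66e-16) and sterol synthesis (7.74e-14) were higher, and interferon-stimulated genes (2.36e-10) and collagens (3.42e-07) were lower. With the trends in transcript length and GC content removed, the medians went from 0.70 to 0.36 for ribosomal proteins, from 0.53 to 0.17 for the respiratory chain, from 0.59 to 0.53 for sterol synthesis, from -0.71 to -0.80 for interferon-stimulated genes and from -0.62 to -0.39 for the collagens, with adjusted p of 5.28e-13, 0.000451, 2.37e-15, 2.26e-16 and 0.000417. With equal variances in the groups 6430 genes passed, and with a t distribution of 4 degrees of freedom 0 passed, where an unadjusted normal p under 0.05 was reached by 5498.

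In SDF1_SKHS over DMSO, 3246 of 17936 genes were higher and 3432 lower. GDF15 (3.67 ± 0.28), TRIB3 (3.17 ± 0.17), CHAC1 (2.94 ± 0.18) and CDKN1A (2.51 ± 0.11) were higher, and PIF1 (-3.60 ± 0.24), the helicase gene RTEL1 (-3.59 ± 0.19), IGFN1 (-3.55 ± 0.26), MEGF6 (-2.85 ± 0.11) and CCNL2 (-2.25 ± 0.10) were lower. The proteases MMP1 (-1.62 ± 0.18), MMP3 (-1.34 ± 0.10) and MMP13 (-1.64 ± 0.26) were lower, as were CXCR4 (-1.64 ± 0.47), ACAN (-1.29 ± 0.22), SOX9 (-0.44 ± 0.14) and CXCL8 (-0.83 ± 0.18), and ACKR3 was higher (1.25 ± 0.13). Of 34 lists, 14 passed, 8 higher and 6 lower, and 11 of the 14 passed at a correlation of 0.05. Matrix proteases (adjusted p = 0.00291), collagens (2.29e-10), mitosis (9.12e-50), replication (2.19e-24) and interferon-stimulated genes (0.0193) were lower, and sterol synthesis was lower with an adjusted p of 0.0369. At a correlation of 0.05 neither the interferon-stimulated genes nor sterol synthesis passed (adjusted p = 0.162 for each), and among genes with a standard error of at most 0.5 sterol synthesis did not pass (adjusted p = 0.0786). On the higher side, medians were 1.24 for p53 targets, 0.90 for NRF2 targets, 0.77 for ribosomal proteins and 0.60 for the ATF4 list. The respiratory chain had a median of 0.41, and of 0.15 with length and GC trends removed. With at least a 2-fold change 2014 genes passed, and with a t distribution of 4 degrees of freedom 2407.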

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

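The minimum of a 2-fold change was chosen before the data were examined, and the other changes of setting here were added after the table had been seen. With it, 993 genes passed for SDF1 over DMSO, 4 for SDF1_AS4 over SDF1, 825 for SDF1_SKHS over SDF1, 672 for SDF1_SKHS over SDF1_AS4, 655 for SDF1_AS4 over DMSO and 2014 for SDF1_SKHS over DMSO. Of SDF-1α-changed genes, 2 then moved back and 0 further with astragaloside IV, 37 back and 82 further with SKHS, and 1 gene changed the same way with both products. Fewer genes can pass a second criterion, so these falls follow from its construction. At an adjusted p of 0.01 the counts were 7 changed, 3 back and 1 further with astragaloside IV, 685 back with SKHS and 2 the same way with both. With only genes of a standard error of at most 0.5 tested, they rose to 190 changed, 73 back and 41 further with astragaloside IV and 83 with both, where fewer genes are tested by construction. With a t distribution of 4 degrees of freedom, 1092 genes passed for SDF1 over DMSO, 1350 for SDF1_SKHS over SDF1, 2407 for SDF1_SKHS over DMSO, and 0 for SDF1_AS4 over SDF1, SDF1_SKHS over SDF1_AS4 and SDF1_AS4 over DMSO (an unadjusted normal p under 0.05 was reached by 2970, 4890 and 5498 genes). Genes moved back and further then numbered 66 and 128 with SKHS and 0 and 0 with astragaloside IV, and 0 changed with both. The heavier tails of this distribution raise every p-value, so these falls too follow from construction. With equal variances, 5708 genes passed for SDF1_SKHS over SDF1_AS4 and 6430 for SDF1_AS4 over DMSO, since the shared libraries leave the spread.

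At a correlation of 0.05, 8 lists passed for SDF1 over DMSO, and with length and GC trends removed 12 passed for SDF1_AS4 over SDF1, 10 of them lower; the cause was not tested. The other 69 of 104 summary counts under these settings stayed within 1.5 times the value reported. Of 3443 values of named genes and of lists, 3056 kept their direction and side of the threshold, 362 no longer passed and 23 came to pass. For SDF1_AS4 over DMSO with the trends removed, H2BC12 moved to -0.073 and RPS27 to -0.024, both positive without this step, and the cause was not tested. Of the 65 genes changed with astragaloside IV, 10 were also called with the trends removed, and 54 others were called then.

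No paired analysis was possible because the table holds no value per sample. For the same reason other normalizations, count filters, pseudocounts, tests, a replicate block, leaving out each replicate and other splits of the samples were not run, and whether 1 culture decides any value is open. The depth that limits each gene is unknown, and its effect is seen only in the implied standard errors, from a median near 0.15 up to 4.08.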

Other observations

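Several groups that did not pass as lists in a deposited comparison held genes with changes past the threshold, and the genes of these first paragraphs were chosen after their values were seen. In the authors' deposited table, the metallothioneins, which bind zinc and copper, rose with SDF-1α for MT1X (0.64 ± 0.09) and MT2A (0.34 ± 0.10) and fell with SKHS for MT1X (-1.50 ± 0.09), MT2A (-0.98 ± 0.18) and MT1G (-2.47 ± 0.62). MT2A rose further with astragaloside IV (0.49 ± 0.11). The 8 measured genes of the list had an adjusted p of 0.0623 for SDF1_SKHS over SDF1. Among 36 inflammatory genes with a value for SKHS, 9 fell and 1 rose (list adjusted p = 0.112), and the chemokine CCL2 (-1.20 ± 0.12 in this comparison, 0.77 ± 0.13 with SDF-1α), the growth factor CSF2 (-1.73 ± 0.40) and the apoptosis inhibitor BIRC3 (-0.72 ± 0.21, 1.02 ± 0.24 with SDF-1α) were among those that fell.

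Of 29 immediate early and ERK feedback genes, 8 rose and 6 fell with SKHS (8 and 8 adjusted over the list alone; list adjusted p = 0.973). Of these, FOS (-1.71 ± 0.17), FOSB (-1.48 ± 0.45), EGR1 (-1.36 ± 0.12) and MYC (-0.61 ± 0.08) fell, while ATF3 (2.29 ± 0.15) and the ERK phosphatases DUSP4 (0.73 ± 0.16), DUSP5 (0.85 ± 0.10) and DUSP6 (0.73 ± 0.14) rose. Of 25 lysosome and autophagy genes, 7 rose and 5 fell with SKHS (list adjusted p = 0.311), and 6 rose and 10 fell with SDF-1α (0.188). The transcription factor TFEB (1.11 ± 0.16) and the autophagy receptor SQSTM1 (0.71 ± 0.07) rose with SKHS, and CTSD (-0.86 ± 0.11) and GPNMB (-0.81 ± 0.09) fell with SDF-1α. Of 28 cartilage matrix genes, 3 rose and 6 fell with SDF-1α (1 and 6 adjusted over the list alone; list adjusted p = 0.313), with COL11A2 (-1.70 ± 0.19), CHAD (-2.52 ± 0.60) and SNORC (-1.18 ± 0.25) lower and LUM (1.49 ± 0.47) higher.

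Of the tests below, that of sign sharing among genes changed with astragaloside IV, the removal of both trends together, the 3 tests on falls of at least 2-fold and the counts by gene list were chosen only after the result had been seen. The first pattern is that the 65 genes changed with astragaloside IV were short and GC-rich when higher and long and GC-poor when lower. With the trend in transcript length removed 17.5% of the annotated changed genes still passed, and with the trend in GC content removed 19.0%, while their median size went from 0.44 to 0.34 in both cases, and with both removed 8 of 63 passed with a median size of 0.27, against a median implied standard error of 0.111. Most calls therefore ended because sizes near the threshold shrank, and all of them kept their sign. Under the rules written in advance, both trends remain candidates for this pattern. Library preparation or RNA integrity that differed between the groups is a candidate explanation for part of it, but neither was measured here. Chance values of the shared SDF1 libraries were weighed by the share of these genes opposite in SDF1 over DMSO and alike in SDF1_SKHS over SDF1, which was 41.5% against 38.5% to 66.2% in simulations. That share does not decide, although the simulations gave at most 1 called gene against 65, and a response to astragaloside IV that itself follows length or GC content stays open, as no test here separates it.

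The second pattern is the 3179 genes lower with SDF-1α and, among them, the excess of large falls, 870 at 2-fold or more against 123 rises. The values argue against a length trend or a GC trend as the whole cause, since 89.6% and 84.6% of the annotated lower genes still passed with each removed, and of the excess of 819 annotated falls over 121 rises at 2-fold 96.7% and 80.8% was left (78.5% with both removed), so part of the excess may follow GC content. With both trends removed, 79.2% of the annotated lower genes still passed, so part of these calls may follow the trends too. An annotated retained-intron transcript was more frequent than among genes of like precision, length and GC content by 11.02 percentage points for lower genes (65.0% against 54.0%) and by 8.28 for those at least 2-fold lower (57.1% against 48.9%), each with a permutation p of 0.0001, two-sided, the smallest that 10000 permutations can give. A lower share of unspliced or intron-retaining RNA in the SDF1 than in the DMSO libraries is a hypothesis, by RNA handling or regulated splicing. Exon number was not matched, and lower genes had a median of 12 exons against 8 for higher genes and 8 for genes not past the threshold. With SKHS the unmatched share was also raised, at 60.0% for lower and 55.4% for higher genes against 46.6% for genes not past the threshold. Annotation alone therefore does not decide this hypothesis, and no reads in introns were available to test it. The solvent named for the DMSO group alone, and SDF-1α itself, stay open and untested as causes.

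The third pattern is that SKHS moved 1101 SDF-1α-changed genes back and 1886 further, and astragaloside IV 25 back and 12 further. Whether chance values of the shared SDF1 libraries added to the genes moved back is not decided, since the 100 simulations of unchanged products held at most 3 called genes for SKHS and 1 for astragaloside IV. With SKHS the genes moved back were 645 and 456 by direction against 533 and 513 at independence, and among precisely measured genes 1064 in all against 1345, and, in 7 lists picked among 34 and with no test between them, 19 back and 0 further of 21 SDF-1α-changed sterol synthesis genes, 14 and 1 of 15 mitosis genes, 14 and 4 of 24 hypoxia and glycolysis genes, 11 and 2 of 24 interferon-stimulated genes, 3 and 19 of 22 replication genes, 2 and 16 of 19 p53 targets and 0 and 46 of 56 ribosomal protein genes. Nearly all sterol synthesis, mitosis, replication and p53 target genes moved the same way with SKHS, so their counts here follow from that direction. Such counts add no evidence that SKHS acts on the SDF-1α response. For both products, a solvent shared with the DMSO group but absent from the SDF1 group would also move genes back, which the labels leave open. For astragaloside IV, 19 genes moved back and 16 further with both trends removed, so the trends may account for part of the excess of genes moved back. Whether either product acts through CXCR4 was not tested by this design. It also has no group with a product and without SDF-1α, so whether the changes with a product need SDF-1α was not tested.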
